A study of Mus musculus with 6 samples.

How the data were processed

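RNA of M-CSF-cultured macrophages, called M2-like by the labels and derived from mice given WT or c-Maf KO fetal liver cells, was hybridised to 1-colour Agilent mouse arrays, with 3 WT and 3 c-Maf KO samples. Scanner files of 5 arrays were used, from WT replicates 1 to 3 and c-Maf KO replicates 2 and 3. A scanner file of c-Maf KO replicate 1 was not analysed here, and this sample enters only through the deposited value table. The labels do not say whether the replicates came from separate mice. The p-values of single genes thus measure the spread between these samples, which may be technical.

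The scanner values are spot intensities that the authors extracted with Agilent Feature Extraction version 10.7.3.1, per the submitters' processing notes and the file headers. Per the file headers, spatial and multiplicative detrending were on, background correction was off, and surrogates were allowed for dim spots in the processed intensity. The authors' value table holds ratios: its log2 values, centred over the 5 arrays, followed the scanner signals scaled to the 75th percentile, and the median log2 ratio of each probe over the 6 samples was 0. It was therefore read as a linear ratio to the probe's median, with 55821 probes, of which 140 were absent from the list of non-control probes. The median log2 ratio of the columns was 0.024, 0.0070 and -0.0088 for WT replicates 1 to 3 and -0.057, 0.068 and -0.054 for c-Maf KO replicates 1 to 3. How the authors filtered or floored low values is not given in the sources used here.

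From the scanner files, control spots and spots flagged as non-uniform or population outliers were left out, which took 134 to 167 of 59305 spots per array. The processed intensity was divided by the array's 75th percentile, non-positive values were set to the array's smallest positive one, log2 was taken, and spots of one probe were averaged. This gave 55681 probes, of which 13 were dropped because all their spots on an array were flagged. A probe was kept where it was well above background on at least 2 arrays, which left 28273. Names came from the array files, updated through RefSeq accessions of GRCm38.p6 for 28026 probes; coordinates are those of the files (mm9). A gene was represented by its kept probe of highest mean signal, giving 20252 genes or unnamed features. Of 5573 genes with several kept probes, 2390 had probes with differences of opposite sign, and 89 had probes more than 1 log2 unit apart.

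The arrays had 48.9% to 50.5% of probes well above background and no saturated probe, and the number of arrays limits the precision. All 5 arrays lay on slide 1 with scan 1, so no block for slide or scan could be fitted. The WT arrays lay in row 1 of the slide and the c-Maf KO arrays in row 2, so row and genotype cannot be told apart. WT replicates 1 and 3 have a shared tag in their file names. The SD of their log2 differences was 0.311, against 0.309 and 0.311 for the other WT pairs, so they were kept as separate samples. This spread over all genes cannot show whether they share a donor.

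Differences are log2 c-Maf KO minus WT, so negative values are lower in c-Maf KO. They were tested with limma version 3.58.1 in R version 4.3.3, using lmFit and eBayes and Benjamini-Hochberg adjusted p under 0.05, without a fold threshold. This was done on the 5 arrays and again on log2 of the value table with all 6 samples. Where a probe was not well above background in any array of a group, the fold is given as a bound. The dim group's level was then the mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. Before the data were examined, 44 gene lists were fixed. The 43 lists with 5 or more kept genes were tested with camera at a preset inter-gene correlation of 0.01, adjusted over lists. At this preset the p-value sets a list's genes against other genes. It does not measure how the list as a whole varies between samples, which the estimated correlation and fry take into account.

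The genes to be named were fixed by rule: the Maf probes, up to 15 called genes in each direction with proper gene symbols and groups that do not overlap, the kept members of the list of published readouts, up to 4 called members of each list, and up to 2 bright members that were not called, where a contrast within a list is described. That last part was limited to the stromal and resident macrophage lists after the values were seen. The rule takes Maf, Masp1, Hrh1, the readouts, and Sparc, Tagln, Igf1 and C1qc. Every other gene named was chosen after its values were seen.

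The alternatives were normexp background correction with offset 50, quantile normalization, the 75th percentile over detected probes, other filters on dim probes, and the mean of a gene's probes. Further ones were eBayes with a trend and robust option (statmod version 1.5.0), array weights, the value table, a replicate block, WT replicates 1 and 3 averaged, each replicate left out, other thresholds, an estimated inter-gene correlation, fry, and lists reduced to genes in 1 list. Covariates for stromal genes and for Xist, and the list tests without stromal genes, were added after seeing the data. The covariates were applied to the call count of the value table and to the list count only, a limit set after it was seen that Xist follows genotype and turns many signs. A test of dilution on a hand-picked set of macrophage genes was also run after seeing the data, gave no answer, and was left out. A test of donor sex on the called genes was left out too, because the selection of these genes fixed its outcome.

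The code was tested on simulated data with 200 genes changed among 20252, using the measured means and spreads, in 20 runs. The other genes of the cell cycle list were also shifted by 0.5, and count among the calls but not the false calls. Noise was drawn separately for each gene, so genes that vary together were not simulated. In the 5-array fit, 24.6% of genes changed by 0.5 log2 units, 62.1% of those changed by 1, 84.5% of those changed by 2 and 97.0% of those changed by 4 were recovered, with 9.35 false calls in 152 calls per run. In the 6-sample fit these shares were 39.3%, 75.7%, 94.1% and 98.3%, with 9.05 false calls in 173 calls per run.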

Results

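The series addresses what the transcription factor c-Maf, encoded by Maf, controls in macrophages with an M2-like state. Gene expression was measured in cultures from mice that had received fetal liver cells of either genotype, 3 samples per genotype. M-CSF, the growth factor that drives macrophage differentiation, was the only cytokine named for the medium. The 75th percentile of the processed intensity lay between 411 and 495 on the 5 arrays, and 27225 to 28140 of 55681 probes per array were well above background. The first principal component of the value table held 36.0% of the variance and set the WT samples (-25.0 to -9.62) apart from the c-Maf KO samples (17.6 to 21.6). WT replicate 1 lay nearest to the c-Maf KO samples.

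Maf was the targeted gene, and its signal was low in each c-Maf KO sample. The main Maf probe (chromosome 8, 118227736 to 118227795, mm9) measured 2.11 ± 0.048 in WT (SD, n = 3) and -2.01 ± 0.33 in c-Maf KO (SD, n = 2), in log2 units relative to the array's 75th percentile. It fell by 4.12 on the log2 scale (SE 0.15, adjusted p = 0.0107), so WT was 17.4-fold higher. In the value table, the log2 ratios were 1.92, 1.98 and 2.03 in WT replicates 1 to 3 and -2.22, -2.36 and -1.92 in c-Maf KO replicates 1 to 3 (adjusted p = 0.000555). A second Maf probe (chromosome 8, 118207273 to 118207332) was at least 6.69-fold higher in WT and not well above background in c-Maf KO (adjusted p = 0.00115 over probes). CB193388, an expressed sequence tag probed 2407 bases from the main Maf probe (chromosome 8, 118225329 to 118225388), was at least 24.9-fold higher in WT (adjusted p = 0.00683). It lies between the main and the second Maf probe, and whether it is part of the Maf transcript was not tested. Which of these positions lie within the deleted part of the gene is not given in the sources used here. The Maf call was lost without WT replicate 1, 2 or 3 (adjusted p = 0.0978, 0.159 and 0.140), at differences of -4.15, -4.11 and -4.10.

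**Figure D1:**
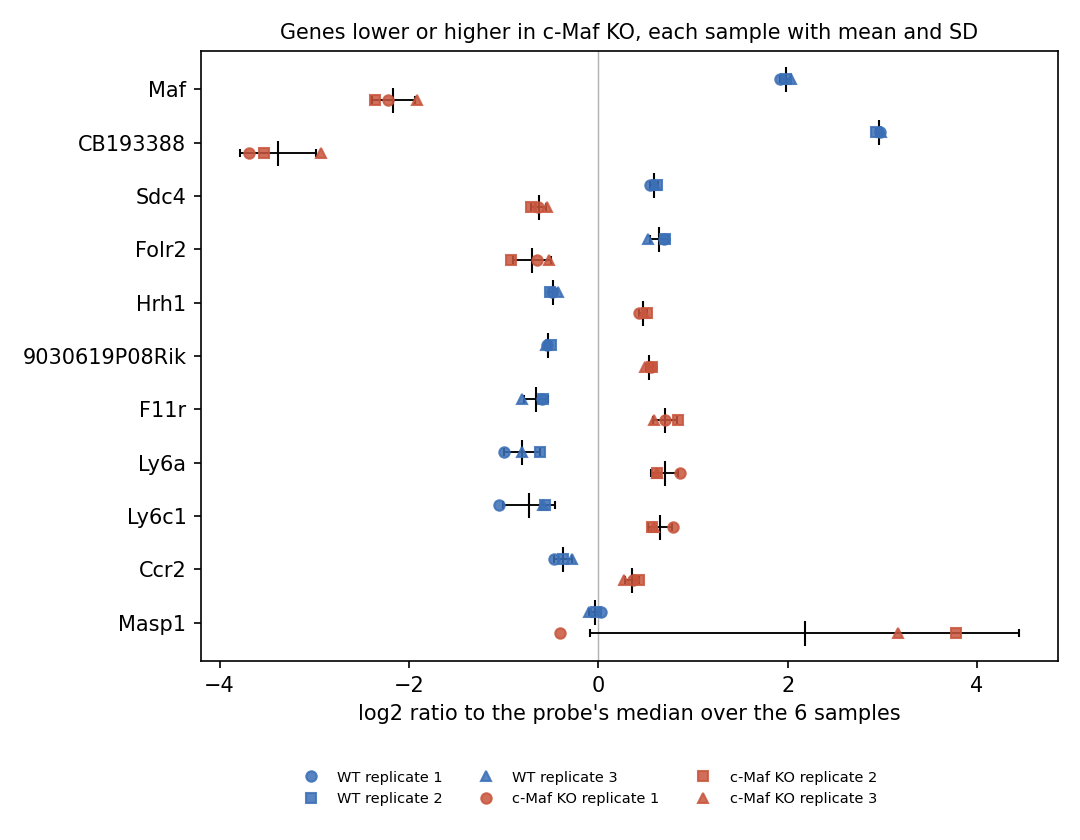
Log2 ratio to the probe's median over the 6 samples (x axis) for 11 genes (y axis), from the authors' value table, with points as samples and black bars as the group mean with SD (n = 3). Maf, CB193388, Sdc4 and Folr2 are lower in each c-Maf KO sample than in any WT sample, while Masp1 is high in c-Maf KO replicates 2 and 3 (3.78 and 3.16) and at -0.41 in replicate 1.

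Besides Maf and CB193388, 5 features passed the test on the 5 arrays, all higher in c-Maf KO, for 7 calls among 20252. Hrh1, the histamine H1 receptor, rose 1.96-fold (log2 difference 0.97, SE 0.057, adjusted p = 0.0486). The transcript 9030619P08Rik rose 2.09-fold (1.06, SE 0.062, adjusted p = 0.0486). Both also passed in the value table with 6 samples (0.95 and 1.07, adjusted p = 0.0115 and 0.00738). A second, dimmer Hrh1 probe measured -0.25 (SE 0.068), and with the mean of both probes the difference was 0.36 (adjusted p = 0.242). The Hrh1 call was also lost with quantile normalization, the 75th percentile of detected probes, no filter on dim probes, probes above background on all 5 arrays and array weights (adjusted p = 0.05995, 0.0535, 0.0953, 0.0511 and 0.0553). The 9030619P08Rik call was lost with the last 3 of these settings, at the same adjusted p. On the 5 arrays neither was called when any 1 of the replicates was left out, with differences of 0.96 to 0.99 for Hrh1 and 1.04 to 1.09 for 9030619P08Rik. In the value table both were called without WT replicate 1 or c-Maf KO replicate 1, and 9030619P08Rik also without c-Maf KO replicate 3. There both calls were lost after quantile normalization and without a filter on dim probes, and Hrh1 also with the mean of a gene's probes. Masp1, a serine protease of the lectin pathway of complement, was at least 2.68-fold higher in c-Maf KO replicates 2 and 3 and not well above background in WT (adjusted p = 0.043). Probes for regions on chromosome 9 (56654525 to 56654584) and chromosome 1 (75079363 to 75079422) were at least 2.49-fold and 2.45-fold higher (adjusted p = 0.00133 and 0.0179). They too were not well above background in WT. In the value table, Masp1 and these 2 regions were at -0.41, -0.30 and 0.10 in c-Maf KO replicate 1, near the WT values, and did not pass (adjusted p = 0.458, 0.441 and 0.363). On the 5 arrays the Masp1 call was also lost with normexp correction, quantile normalization and no filter on dim probes (adjusted p = 0.0928, 0.05995 and 0.0909). The chromosome 1 region was lost with normexp correction and no filter (0.0971 and 0.0637). Quantile normalization called 5 features, 3 higher and 2 lower, against 5 higher and 2 lower, and without WT replicate 1, 2 or 3 only the chromosome 9 region was called. Its WT values (-6.40, -6.42 and -6.46) lay below the lowest signals well above background (-4.21, -4.29 and -4.31). Their small spread is that of undetected signal, so this call is no sturdier for it. With normexp correction its difference was 0.76 (adjusted p = 0.0404), against 3.47. Without c-Maf KO replicate 2 or 3 there were 14 and 11 calls.

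The value table, which holds the 3 against 3 comparison of the study, gave 7 calls, 4 of them shared with the 5 arrays. It includes the same 5 arrays, so the shared calls do not replicate each other. The other 3 calls of the value table were Sdc4, F11r and Ly6a. Sdc4, the heparan sulfate proteoglycan syndecan-4, fell by 1.22 (SE 0.065, adjusted p = 0.00738). F11r, the junctional adhesion molecule A, rose by 1.37 (SE 0.097, adjusted p = 0.0268). Ly6a, which encodes Sca-1, rose by 1.51 (SE 0.12, adjusted p = 0.0487). On the 5 arrays their differences were -1.22, 1.37 and 1.42 (adjusted p = 0.0597, 0.130 and 0.130). Without WT replicate 1 the value table gave 95 calls, 89 of them higher in c-Maf KO, while without WT replicate 2 or 3, or c-Maf KO replicate 2 or 3, it gave 3, 3, 2 and 4, and without c-Maf KO replicate 1 it gave 9. Sdc4, F11r and Ly6a were not called without WT replicate 2 or 3 or c-Maf KO replicate 2, nor without a filter on dim probes. F11r and Ly6a were also not called without c-Maf KO replicate 1 or 3 or after quantile normalization, and Ly6a not with the mean of a gene's probes. The WT and c-Maf KO samples did not overlap for 4046 of 20252 genes, where chance gives 10%.

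A variance model with a trend over signal and robust estimation, one of the alternatives fixed beforehand, called 80 genes on the 5 arrays and 84 in the value table. The 35 called in both included 22 higher and 13 lower in c-Maf KO. Their samples did not overlap in any of the 35, which selection for a group difference makes likely. Both sources hold the same 5 arrays, so calls in both are not independent evidence. Among those higher, Ly6g measured 1.55, Ly6a 1.51 and Ly6c1 1.39 in the value table. Ccr2, the receptor for Ccl2 on inflammatory monocytes, measured 0.73 and Cd300lf, an inhibitory myeloid receptor, 1.32. The chemokine gene Cx3cl1 (0.88), the lipid enzymes Lpcat2 (0.90) and Sphk1 (0.57), the transcription regulator Id1 (0.67) and the glycolytic gene Aldoc (0.56) were also higher. Those lower included Folr2, a folate receptor of tissue macrophages, at -1.34. The tetraspanin gene Tspan33 measured -1.02, the integrin gene Itga9 -0.92, Gprc5c -0.67, the cell cycle inhibitor gene Cdkn1c -0.66 and Nfatc2 -0.45. Lrmda was not well above background in c-Maf KO and at least 4.04-fold higher in WT. None of these genes apart from Maf, CB193388, Hrh1, 9030619P08Rik, Sdc4, F11r and Ly6a passed the planned test in either source. A dimmer Ly6c1 probe measured 0.11 (SE 0.36) and one of the 3 Cd300lf probes -0.041 (SE 0.15) on the 5 arrays. The probes of Ly6a, Ly6c1, Ly6g and 9030619P08Rik lie near each other on chromosome 15 (from 74825553, 74875495, 74989023 and 75260421, mm9). Whether these genes changed separately was not tested.

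Among the 12 measured genes on the list of published readouts of c-Maf and of macrophage polarisation, Maf fell and none rose over all genes tested. Adjusted over the list alone, Maf fell and Ccr2 and Arg1 rose, on the 5 arrays and in the value table. The list was drawn up with knowledge of the study, so this is not independent evidence. Arg1, the arginase of alternatively activated macrophages, was 1.55-fold higher in c-Maf KO (log2 difference 0.63, SE 0.12, adjusted p = 0.266 over all genes and 0.0120 over the list alone). Ccr2 was 1.65-fold higher (0.72, SE 0.084, adjusted p = 0.170 and 0.00243). The samples of both genes did not overlap between genotypes in the value table, nor did those of Mrc1 and Tgfb1, which were lower in c-Maf KO (-0.24 and -0.16 there) and did not pass. Csf1r, the M-CSF receptor, measured -0.081 with a 95% interval of -0.28 to 0.12. The mannose receptor gene Mrc1 measured -0.25 (-0.52 to 0.027), Tgfb1 -0.21 (-0.39 to -0.028) and Vegfa 0.11 (-0.10 to 0.32). The differences were -0.086 for Irf4, -0.16 for Cd86, -0.090 for Tnf, -0.081 for Il1b and 0.031 for Nos2, and none of these 5 passed. Without c-Maf KO replicate 2 the Mrc1 difference was -0.096, and without replicate 3 it was -0.395. Over all alternatives Cd86 ranged from -0.28 without c-Maf KO replicate 2 to -0.040 without replicate 3, Csf1r from -0.13 to -0.018 and Vegfa from 0.077 to 0.16. The signs for Irf4, Tnf, Il1b and Nos2 turned when 1 replicate was left out. Il10, Il12a, Il12b and Il6 were not well above background on at least 2 arrays.

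**Figure D2:**
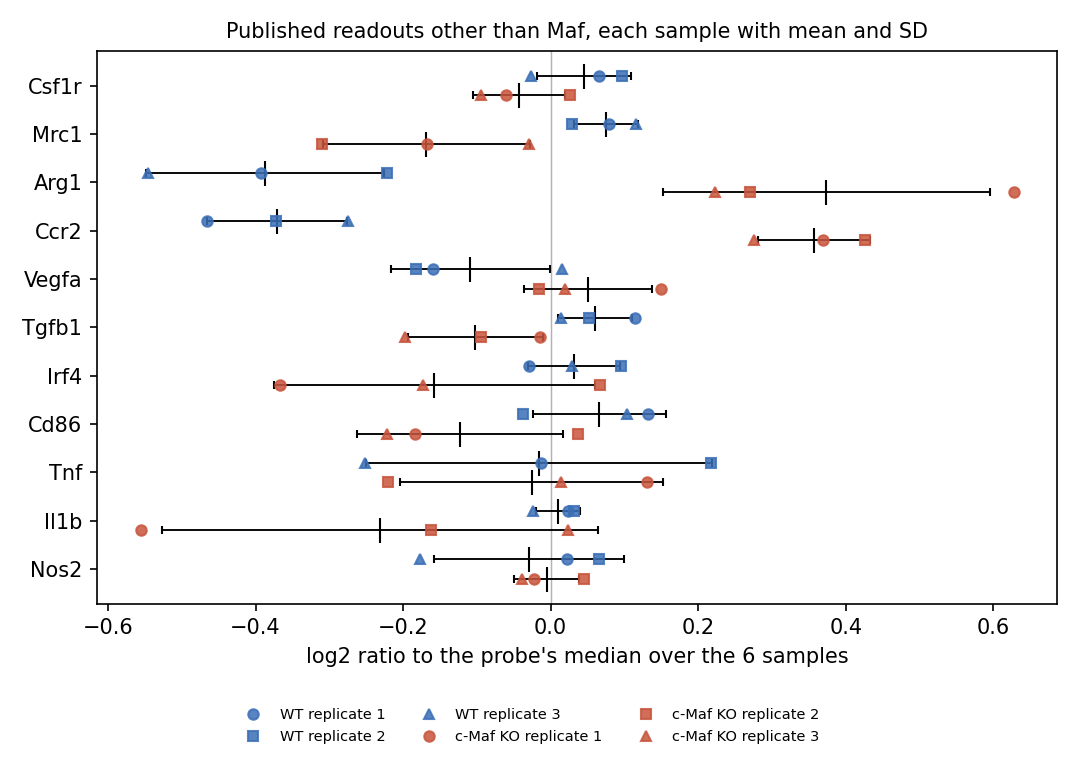
Log2 ratio to the probe's median over the 6 samples (x axis) for 11 readout genes other than Maf (y axis), from the authors' value table, with points as samples and black bars as the group mean with SD (n = 3). Arg1 and Ccr2 are separated between the genotypes, with differences of 0.76 and 0.73, as are Mrc1 and Tgfb1, which are lower in c-Maf KO (-0.24 and -0.16), while the Csf1r, Tnf and Nos2 samples overlap.

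A list of resident macrophage genes, chosen for a link to large Maf factors, shifted down in c-Maf KO when set against other genes. Of 19 measured members, 15 had negative differences, with a median of -0.28 (camera, adjusted p = 0.000749). The adjusted p = 0.829 with an estimated correlation, 0.1997 with genes of no other list, and 0.103 without c-Maf KO replicate 2. The list mean of c-Maf KO replicate 3 in the value table (0.048) lay above those of WT replicates 2 and 3 (0.026 and 0.032), and stromal markers followed genotype in the same samples. No member passed over all genes. Adjusted over the list alone, 8 fell and 2 rose on the 5 arrays, and 5 fell and 1 rose in the value table, where C1qb, C1qc, Adgre1 and Vsig4 did not pass. Folr2 measured -1.37 on the 5 arrays. Stab1, a scavenger receptor, measured -0.79, Gas6, a bridging ligand for uptake of dying cells, -0.74, F13a1 -0.54 and Hpgds -0.45. Without c-Maf KO replicate 2 the Gas6 difference was -0.41, and without replicate 3 it was -1.07. Of the brightest members, Igf1 measured -0.11 and did not pass over the list, while the complement gene C1qc measured -0.38 and was among the 8 that fell on the 5 arrays. Vsig4, a complement receptor of the same list, was among the 2 that rose on the 5 arrays, at 2.06 (SE 0.62, adjusted p = 0.386), with value-table log2 ratios of 0.33, 0.63 and 2.70 in c-Maf KO replicates 1 to 3. Fc receptor genes shifted down (7 of 8 members negative, median -0.17, camera adjusted p = 0.0104, and adjusted p = 0.701 with an estimated correlation). Fcgr1 measured -0.59, Fcrls -0.53 and Fcgrt -0.29, and these 3 fell on the 5 arrays when adjusted over the list alone. In the value table Fcrls and Fcgrt fell and Fcgr1 (-0.44) did not pass. The mean over the Fc receptor list in c-Maf KO replicate 1 there (0.036) lay within the WT values (0.026 to 0.11). On the 5 arrays the Fcgr1 difference was -0.38 without c-Maf KO replicate 2 and -0.80 without replicate 3. The shift of the Fc receptors did not pass in the value table (adjusted p = 0.0609), nor without WT replicate 1 (0.0648) or c-Maf KO replicate 2 (0.162).

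Markers of fibroblasts and stromal cells were higher in c-Maf KO, with all 19 measured members positive and a median of 0.93 (camera, adjusted p = 5.57e-10). The adjusted p = 0.701 with an estimated correlation, and no member passed over all genes or over the list alone on the 5 arrays. Adjusted over the list alone, 15 of the 19 rose in the value table. Sparc, a matrix glycoprotein, measured 0.92 (SE 0.25), Col1a1, a collagen chain, 0.93 (SE 0.28), Acta2, smooth muscle actin, 1.01 (SE 0.30) and Tagln 0.75 (SE 0.22). Another, dimmer Sparc probe measured -0.42 (SE 0.072). The mean log2 ratio over the list was -0.065, -0.89 and -0.68 in WT replicates 1 to 3 and 0.21, 0.16 and 0.54 in c-Maf KO replicates 1 to 3. Genes of matrix remodelling shifted up with them (21 of 26 members positive, median 0.59, camera adjusted p = 3.55e-05, and adjusted p = 0.701 with an estimated correlation). In that list the protease inhibitor gene Timp1 measured 1.07, Spp1 (osteopontin) 0.88 and the urokinase gene Plau 0.76. These 3 rose when adjusted over the list alone, and Timp2 fell. Among the WT samples, Timp1 and Spp1 were highest in replicate 1 (-0.30 and -0.28 in the value table), and Plau in replicate 2 (-0.17).

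**Figure D3:**
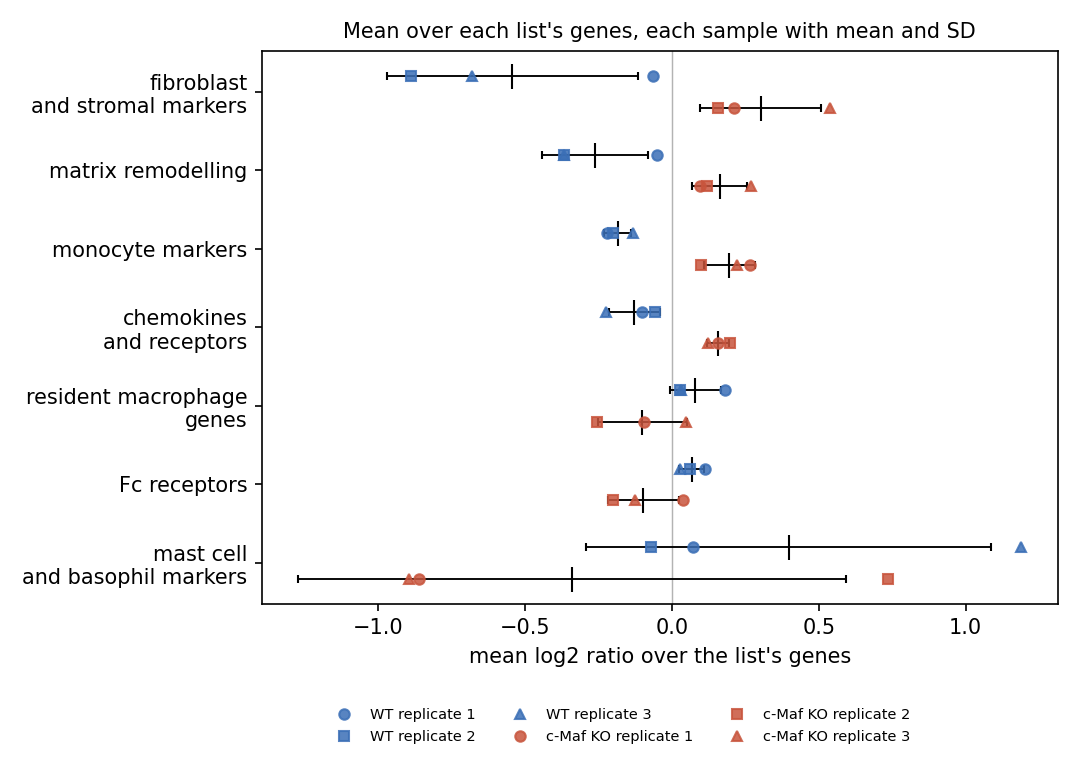
Mean log2 ratio over each list's measured genes (x axis) for 7 gene lists (y axis), from the authors' value table, with points as samples and black bars as the group mean with SD (n = 3). The stromal mean of WT replicate 1 (-0.065) lies near the c-Maf KO samples (0.16 to 0.54), and the mast cell means vary within both genotypes.

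Monocyte markers and chemokine genes shifted up (camera, adjusted p = 0.00897 for both, and adjusted p = 0.701 with an estimated correlation). Among 11 monocyte markers 7 were positive, with a median of 0.15, and Ly6c1 (1.31) and Ccr2 (0.72) rose when adjusted over the list alone. Ly6c1 lies near Ly6a and Ly6g on chromosome 15. Of 25 chemokine and receptor genes 17 were positive, with a median of 0.19. Cxcl12, a stromal chemokine, measured 1.30 and Ccl22, a ligand of Ccr4, was at least 2.17-fold higher in c-Maf KO and not well above background in WT. Both rose with Ccr2 when adjusted over the list alone. The monocyte shift was lost without c-Maf KO replicate 3 (adjusted p = 0.138) and the chemokine shift without WT replicate 3 (0.0510). With genes of no other list neither passed (adjusted p = 0.0542 and 0.0867).

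Genes of arginine and polyamine metabolism shifted up by a small amount, with 16 of 18 members positive and a median of 0.087 (camera, adjusted p = 0.0104). The adjusted p = 0.701 with an estimated correlation, 0.0542 with genes of no other list, and 0.0816 without c-Maf KO replicate 3. Genes of the oxidative stress response also shifted up (14 of 20 positive, median 0.089, adjusted p = 0.0150, and adjusted p = 0.905 with an estimated correlation and 0.0542 with genes of no other list). The heme oxygenase gene Hmox1 (0.39), the glutathione transferase gene Gsta3 (0.59) and the cystine transporter gene Slc7a11 (0.51) rose when adjusted over that list alone. The shift was lost without WT replicate 1 or 3 or c-Maf KO replicate 2 (adjusted p = 0.111, 0.0913 and 0.184). Genes of TLR and NF-kB signalling shifted down (25 of 34 negative, median -0.11, adjusted p = 0.0154, and adjusted p = 0.701 with an estimated correlation). Their shift was lost without WT replicate 2 or c-Maf KO replicate 2 (adjusted p = 0.0893 and 0.184). Clec4e, a receptor for mycobacterial glycolipid, went against it at 0.73 and rose when adjusted over the list alone, while Relb fell. In the value table Clec4e also rose, and Relb did not pass. There the mean over the TLR and NF-kB list in c-Maf KO replicate 1 (0.030) lay within the WT values (0.016 to 0.044). The oxidative stress mean of c-Maf KO replicate 3 (-0.0031) lay below that of WT replicate 2 (0.0043). With the directional form of fry, a test that rotates residuals, none of the 9 shifted lists passed (adjusted p = 0.248 to 0.513). Its mixed form, which asks for no common direction, gave unadjusted p = 6.29e-05 (chemokines and receptors) to 0.0631 (stromal markers) for these lists. Mixed fry gave 0.000134 for alternative activation, 0.000193 for classical activation and 0.163 for interferon-stimulated genes, which camera did not call shifted.

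The lists for alternative activation (28 members, median -0.018, adjusted p = 0.827) and classical activation (26 members, median -0.086, adjusted p = 0.827) did not shift. Nor did the interferon-stimulated genes (median 0.0057, adjusted p = 0.770), the genes of MHC class II presentation (0.0049, adjusted p = 0.182), glycolysis (0.024, adjusted p = 0.171), oxidative phosphorylation (0.030, adjusted p = 0.140) or the cell cycle (0.0033, adjusted p = 0.477). In the value table oxidative phosphorylation (median 0.048) and hypoxia and angiogenesis (0.11) shifted up, both at adjusted p = 0.0477 (0.997 and 0.929 with an estimated correlation). Within the alternative activation list, adjusted over it alone, Arg1 and Ccl22 rose while Stab1 and Folr2 fell. Immune suppression and checkpoint genes had a median of -0.091 and a mean of 0.15 (adjusted p = 0.827), and Havcr2, which encodes Tim-3, measured 0.78 and rose when adjusted over the list alone. In all, 6 lists shifted up and 3 down among the 43 tested, and the median, mean and test differed in sign in 9 lists, none of them shifted.

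The genotypes also differed in sex-linked transcripts, of which 4 were kept, too few for a list test. Xist, the RNA of the inactive X chromosome, had value-table log2 ratios of 2.66, 1.28 and 2.92 in WT replicates 1 to 3 and -1.33, -3.26 and -1.28 in c-Maf KO replicates 1 to 3. It did not pass over all genes (difference -4.24, SE 0.68, adjusted p = 0.135). The Y-linked genes Eif2s3y, Ddx3y and Uty were higher in c-Maf KO by 0.94, 0.80 and 0.76. In WT replicate 2, Eif2s3y and Ddx3y stood at -0.11 and 0.024, against -0.96 and -0.95 in replicate 1 and -1.10 and -1.20 in replicate 3. Xist, Eif2s3y and Ddx3y thus set WT replicates 1 and 3, which share a name tag, apart from replicate 2. For Uty, WT replicate 3 (-0.49) lay between replicates 1 and 2 (-0.85 and -0.15). Whether WT replicates 1 and 3 share a donor was not tested. The Ddx3y samples overlapped, with c-Maf KO replicate 1 at -0.024. Adjusted over the list alone, Xist fell and the 3 Y-linked genes rose in the value table, while on the 5 arrays Xist fell, Uty rose, and Eif2s3y and Ddx3y did not pass. Xist and the 3 Y-linked genes were all well above background on each of the 3 WT arrays. On the 2 c-Maf KO arrays the Y-linked genes were well above background on both, and Xist on 1.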

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

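The covariates for stromal genes and Xist and the list tests without stromal genes were chosen after seeing the data. Of the 7 calls, 5 higher and 2 lower, normexp correction gave 21 (13 and 8), probes above background on all 5 arrays gave 1 (0 and 1), and the trend and robust model gave 80 (50 and 30). Quantile normalization, array weights and no filter each gave 5 calls, 3 of them higher. An adjusted p under 0.01 left 2 (1 and 1), and WT replicates 1 and 3 averaged left 1 (1 and 0). Leaving out 1 replicate gave 1 to 14 calls, 1 to 12 higher and 0 to 2 lower; with 1 c-Maf KO array left, that array is assumed to vary like WT. The Maf difference was -4.12 with WT replicates 1 and 3 averaged and -4.35 to -3.89 with a replicate left out (-4.15, -4.11 and -4.10 without WT replicates 1 to 3), with fewer residual degrees of freedom. The value table, with 7 calls, gave 2 without a filter, 22 with probes above background on all 5 arrays, 3 after quantile normalization, 84 with the trend and robust model and 2 to 95 with 1 replicate left out. With the stromal mean or Xist as a covariate it gave 0 calls in limma, with 1112 and 1068 genes at an unadjusted p under 0.05; both covariates follow genotype. The 9 shifted lists became 0 with an estimated correlation and 0 with directional fry. They became 5 with genes of 1 list and 3 with Xist as a covariate. The other settings gave 6 to 13. Of the 9, 8 also shifted in the value table, which includes the same 5 arrays.

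Over all genes, same-numbered samples did not deviate together (correlations across genes -0.027, -0.060 and 0.043 for numbers 1 to 3). WT and c-Maf KO samples with different numbers gave -0.049 to 0.076. The correlations thus gave no sign that the numbers pair the samples. They cannot exclude a pairing that affects only some genes. The replicate block gave 0 calls on the 5 arrays in limma (0 higher, 0 lower; 2139 genes at an unadjusted p under 0.05; Maf -4.15), 3 in the value table and 6 shifted lists.

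Signs turned for small differences with 1 replicate left out: Irf4 -0.20 to 0.025, Tnf -0.22 to 0.037, Il1b -0.18 to 0.021 and Nos2 -0.049 to 0.082. The cause of these changes was not tested. A block for slide or scan was not run because all arrays have 1 of each. Masp1, Ccl22 and the called regions on chromosomes 9 and 1, not well above background in WT, have only a lower bound.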

Other observations

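The test of stromal cells, and the locus test without Maf and CB193388 with its bearing on the verdict, were chosen after the result was seen. Mast cell and basophil markers, 7 measured genes, varied within both genotypes: their mean log2 ratio was 0.072, -0.071 and 1.19 in WT replicates 1 to 3 and -0.86, 0.74 and -0.90 in c-Maf KO replicates 1 to 3. The list shifted down in the value table (adjusted p = 0.0400, and 0.929 with an estimated correlation) and did not on the 5 arrays (0.263). Erythroid, hepatocyte, endothelial, lymphoid, eosinophil and neutrophil lists did not shift in either source. Without WT replicate 1, 3 of the 19 stromal genes and 3 of the 26 matrix remodelling genes were among the 95 calls of the value table.

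Of 10 splits of the 6 samples, only 1, the real one, gave 7 calls in the value table, and the highest of the other splits gave 0, but 10 splits are too few for a share under 0.05. A different mix of cell types stays open: 1 of the 8 marker lists of other cell types shifted on the 5 arrays, where 3 in one direction were set as needed and 0 as ruling it out. Donor sex has no valid test here, since the samples of Xist, Eif2s3y and Uty, though not of Ddx3y, do not overlap between the genotypes. It cannot be told apart from genotype and stays open too. A direct effect of c-Maf loss was not tested apart from these.

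Stromal genes higher in c-Maf KO may come from a larger share of stromal cells in those cultures. Markers of 1 cell type would then move together between cultures of 1 genotype, and 18 of the 19 stromal genes were highest in WT replicate 1 among the WT arrays, against 34.8% of other genes. WT replicate 1 exceeded the other WT arrays by a median of 0.77 over these genes, while the c-Maf KO mean still exceeded WT replicate 1 in 18 of 19 by a median of 0.41 in the value table. The abundant stromal transcripts Sparc and Tagln went with the rest. Genes regulated together within cells would also be highest in the same array. The joint rise in WT replicate 1 therefore cannot tell a share of stromal cells from regulation. Regulation of these genes in macrophages by c-Maf was not tested and stays open, as does the place of the arrays on the slide.

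Genes near Maf were tested for variants of another strain carried along with the targeted locus. Called genes were more frequent within 10 Mb of Maf (one-sided Fisher exact p = 0.00335). Both were Maf itself and CB193388, which lies between the Maf probes. Without them, 0 of 260 genes in the window were called by limma, and 34 (13.1%) had an unadjusted p under 0.05, against 11.01% elsewhere (one-sided Fisher exact p = 0.168). With so few calls, and with the test limited to this window, the explanation could neither be excluded nor be supported. Outside the window, Lpcat2, Ccl22 and Cx3cl1, all higher in c-Maf KO, lie near each other on chromosome 8 (from 95443101, 97274709 and 97306185, mm9). Ly6a, Ly6c1, Ly6g and 9030619P08Rik do so on chromosome 15. These genes were picked after their values were seen, and their clustering was not tested.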
